A study of Homo sapiens with 18 samples.

How the data were processed

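The series holds 18 libraries of LoVo cells in 6 groups of 3, MeRIP input, MeRIP IP and RNA-seq libraries of METTL3 WT and of METTL3 K513R cells. For MeRIP-seq, poly(A) RNA was fragmented with zinc chloride, part was kept as input and the rest was immunoprecipitated with an antibody to m6A. RNA-seq libraries were made from total RNA depleted of rRNA with a stranded kit. Samples were grouped by the deposited labels, and every column of values matched 1 sample.

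The authors deposited a table of raw counts per gene for the RNA-seq libraries (61267 genes, 52880 with a count, 20393 named only by an Ensembl identifier). They deposited a table of m6A peaks with raw counts per peak for the 12 MeRIP libraries. In that peak table the deposited fold enrichment of each peak is a ratio of IP over input, per the file headers. The deposited p-value and FDR of each peak, and those of the authors' comparison of the genotypes, are given per the file headers as p-value columns. The deposited score equals the fold enrichment in 100% of the peaks. The authors' deposited difference between genotypes is a log2 value, K513R over WT by its sign against the counts. The authors' notes name Trimmomatic 0.36, featureCounts of Subread 1.5.1, bedtools, deepTools, edgeR 3.12.1 and GRCh38, and the aligner and the peak caller are not given in the sources used here. The RNA-seq counts of MALAT1 and of its antisense gene TALAM1 were nearly equal (483088 and 463885 in K513R replicate 1), so reads over overlapping genes were counted for each of them without regard to strand. For each named gene the share of its exonic length that overlaps another gene was computed.

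RNA-seq counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM factors, filterByExpr by genotype, genotype as the only term, two-sided), with a Benjamini-Hochberg adjusted p under 0.05 as threshold. The filter left 30377 genes and dropped 30890. The biological coefficient of variation was 13.7% in RNA-seq, 10.8% in the inputs and 15.2% in the peaks. Levels are CPM with TMM factors, with the SD over 3 libraries, and fold changes carry the SE of the model. Before the data were examined, 24 gene lists were fixed and tested with camera of limma 3.58.1 on voom values (preset correlation 0.01, adjusted over the lists). An estimated correlation and fry, which tests whether a list moves on balance one way without comparing it with other genes, were alternatives. Genes named in the text were chosen by a rule fixed at the same time. It takes METTL3, METTL14, WTAP, SETD1A and E2F4, the 6 largest rises and the 6 largest falls among genes past the threshold with a mean of at least 5 CPM and libraries that separate the genotypes, with a symbol that is not a clone, LINC, pseudogene or antisense name, up to 3 members with the largest change of each list past camera and of the double-stranded RNA sensing, interferon-stimulated, antigen presentation, retroelement-derived and m6A machinery lists, and 1 member of each other list. Genes named beyond it were chosen after their values were seen, and 1 gene that the rule takes is not reported here. For peaks it takes the 6 largest losses and the 6 largest gains.

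Peak counts were tested with edgeR by the interaction of genotype and IP over all 12 MeRIP libraries, with TMM factors computed within IP and within input libraries. Per library, log2 IP over input was taken from CPM with 0.5 added. These CPM are scaled to the counts of each library in the tested peaks. A negative value thus means weaker enrichment than is typical of these peaks, not IP below input. Peak positions were read along the merged exons of each gene in the exon coordinates of the count table, in place of the planned shares in untranslated and coding regions, because that annotation was not used here. The count table has 0 repeat element entries, so the planned test of retroelements was not run. Genes with a higher or lower peak were compared with the RNA-seq calls by camera and by Fisher's exact test, two-sided. The Fisher background was genes with any deposited peak, whether or not that peak was tested. A comparison of the MeRIP inputs as expression data, with counts summed per gene over non-overlapping peaks, was added after the data were seen, as was a joint edgeR model of RNA-seq and inputs with an assay by genotype term. These input values cover genes with a peak only.

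Alternatives changed 1 choice at a time, except that leaving out the 7SL, 7SK and mitochondrial genes also scaled by library size. Subsets of peaks were refitted, which also gave new scaling factors. They were RLE factors, upper-quartile factors, library size, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block and leaving out each replicate. For peaks they were the stronger peaks by the authors' score, a stricter FDR, a reciprocal overlap of 50% and pairing of input and IP. Peak overlaps used bedtools 2.31.1, and the tables were prepared with Python 3.11.15. The tests were run on simulated data with changes of known size. Each simulation changed 200 features, far fewer than the tests called in the real data, so the shares found do not measure power here. In RNA-seq 26.7% of changes of 1.5-fold, 66.7% of 2-fold and 96.2% of 4-fold were found, with 13 false calls among 25717 genes. In the inputs the shares were 66.2%, 95.3% and 98.3% with 6 false calls, and in peaks 9.6%, 41.4% and 77.4% with 1 false call.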

Results

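LoVo is an established human colorectal cancer cell line, and METTL3 is the catalytic subunit of the enzyme complex that writes N6-methyladenosine (m6A) on mRNA. The series compared LoVo cells with wild-type METTL3 (WT) with cells carrying METTL3 K513R, in which arginine replaces a lysine that the study describes as methylated, to learn what that methylation does. In MeRIP-seq, fragmented poly(A) RNA was sequenced before (input) and after (IP) pull-down with an antibody to m6A. RNA-seq was made from total RNA depleted of rRNA. Each genotype had 3 input, 3 IP and 3 RNA-seq libraries, 18 in all. The RNA-seq gene counts summed to 47105235 to 51886164 per WT library and 47451837 to 53795212 per K513R library. Counts inside the deposited m6A peaks summed to 11076729 to 12491969 per WT IP library, 5905811 to 9198650 per K513R IP library, 5025027 to 6200264 per WT input library and 2625446 to 4847236 per K513R input library, so the K513R MeRIP values rest on fewer counts in peaks. Reads in overlapping peaks of both lists count more than once in these sums. Over non-overlapping peaks the sums were 6229799 to 7073961 per WT IP and 3267034 to 5080385 per K513R IP library. For input libraries they were 2904563 to 3596567 in WT and 1548541 to 2821405 in K513R. The labels number the libraries of a group without saying whether they came from separate cultures, so the p-values measure the spread between these libraries only, which may be technical.

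METTL3 itself (chromosome 14, 21498133 to 21511342, minus strand, GRCh38) stood at 39.2 ± 0.897 CPM (counts scaled to the library total) in WT and 52.0 ± 2.44 CPM in K513R RNA-seq libraries (mean ± SD, n = 3 each, here and below). This was a log2 fold change of 0.41 ± 0.09 (SE; edgeR adjusted p = 0.00116). A count per gene carries no information on an amino acid change, so this level does not check the labels. METTL14, the RNA-binding partner of METTL3 (chromosome 4, 118685392 to 118715433), fell by 0.87 ± 0.11 on the log2 scale, from 66.5 ± 10.1 to 36.4 ± 2.07 CPM. WTAP, the subunit that places the complex at nuclear speckles (chromosome 6, 159725585 to 159756319), rose by 0.42 ± 0.10, from 54.9 ± 4.69 to 73.4 ± 4.33 CPM. SETD1A, an H3K4 methyltransferase named in the series title (chromosome 16, 30957294 to 30984664), fell by 1.46 ± 0.10, from 94.1 ± 6.55 to 34.3 ± 3.32 CPM. E2F4, the transcription factor that the title sets beside it (chromosome 16, 67192155 to 67198918), had 36.0 ± 6.57 CPM in WT and 36.8 ± 5.24 CPM in K513R, a log2 fold change of 0.03 ± 0.14 that did not pass the test (edgeR adjusted p = 0.835). The E2F4 value lies close to 0 and was -0.05 with library-size scaling, and upper-quartile factors gave 0.30, past the threshold.

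The first comparison asked which RNAs differ between the genotypes in RNA-seq. Genes of 7SL, the RNA of the signal recognition particle, held 3.32 ± 0.743% of all gene counts in WT and 26.1 ± 1.04% in K513R, and mitochondrially encoded genes 4.16 ± 0.727% and 0.281 ± 0.0631%. Histone genes held 1.04 ± 0.0379% and 0.245 ± 0.00839%, and ribosomal protein genes 4.25 ± 0.255% and 2.30 ± 0.0289%. All 3 K513R libraries lay on the same side of all 3 WT libraries for these 4 families. With 3 libraries against 3, an exact permutation test of such a share cannot go below p = 0.1. Among genes with a mean of at least 5 CPM over the 6 libraries that separate the genotypes, the largest rises among named genes were in RFPL4A, TRIM72, HTR4, CNDP1, UBE2L5 and C8orf74, all near 0 in WT. TRIM72, a membrane repair protein of muscle (chromosome 16, 31214119 to 31231537), went from 0.0401 ± 0.00297 to 16.9 ± 2.19 CPM, and HTR4, a serotonin receptor (chromosome 5, 148446042 to 148677235), from 0.0393 ± 0.0375 to 15.7 ± 0.623 CPM. CNDP1, a dipeptidase that splits carnosine, went from 0.0535 ± 0.0128 to 16.5 ± 0.857 CPM, C8orf74 from 0.0398 ± 0.0341 to 10.2 ± 1.91 CPM and UBE2L5 from 0.0322 ± 0.03 to 10.2 ± 1.01 CPM. Of their fitted log2 fold changes, that of HTR4 (8.54) was 9.37 without WT replicate 1 and 7.93 without WT replicate 3, and those of C8orf74 (7.91) and UBE2L5 (8.16) were both 8.78 without WT replicate 3. RFPL4A had 2 counts over all WT libraries and 1845 over all K513R libraries, a ratio of 950 (95% counting interval 263 to 7850), and its fitted log2 fold change moved from 9.64 to 12.25 without WT replicate 1. The largest falls were in the mitochondrial tRNA genes MT-TY, MT-TC and MT-TN, in the histone genes H2AC21 and H2AC20, and in the 5.8S rRNA gene RNA5-8SN3. H2AC21 (chromosome 1, 149887469 to 149887965) fell by 6.95 ± 0.18 on the log2 scale, from 355 ± 14.4 to 2.87 ± 1.10 CPM, and MT-TY fell by 7.18 ± 0.50, from 194 ± 84.0 to 1.33 ± 0.184 CPM. The MeRIP inputs, compared below, held H2AC20 at 119.6 ± 1.94 CPM in WT and 120 ± 7.35 CPM in K513R. Its change did not pass there (edgeR adjusted p = 0.9993).

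In the edgeR quasi-likelihood test 12592 of 30377 genes were higher and 11208 lower in K513R at an adjusted p under 0.05, which together is 78.3% of the genes tested. Of these, 9756 were higher and 7799 lower by at least 1 on the log2 scale. In 80.3% of the genes the 3 K513R values lay on one side of the 3 WT values, where chance gives 10%. The median log2 fold change of all genes was 0.13 with TMM factors and 0.39 with upper-quartile factors, so values near 0 depend on the scaling. Without the low-count filter it was 0.65.

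**Figure D1:**
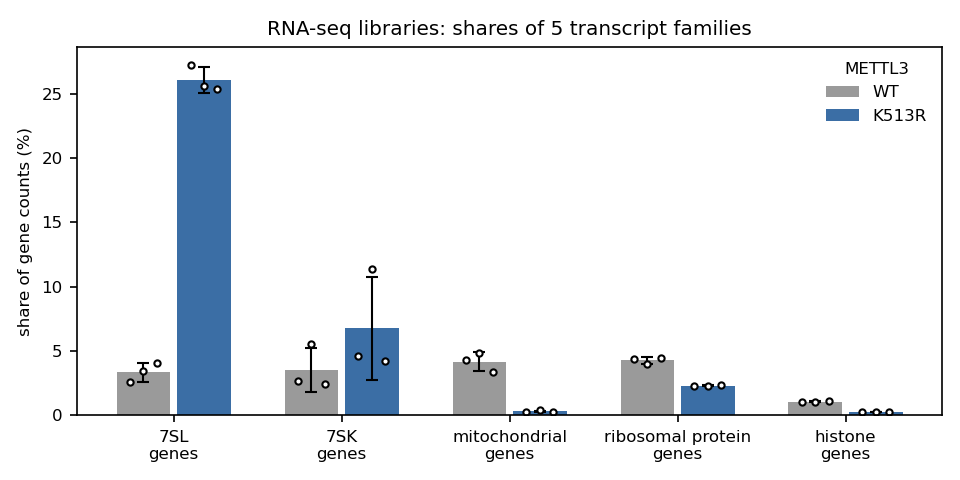
Share of all gene counts, in percent, taken by 5 transcript families in the RNA-seq libraries, with bars for the mean of 3 WT (grey) and 3 K513R (blue) libraries, error bars for the SD and points for single libraries. 7SL genes held 3.32% in WT and 26.1% in K513R, and mitochondrial genes 4.16% and 0.281%. The 7SK genes stood at 3.52 ± 1.73% and 6.74 ± 4.04%.

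Several immune gene groups fixed before the data were examined were higher in K513R. Of the 17 interferon ligands and chemokines measured, 13 rose and 1, the cytokine IL18, fell (median log2 fold change 3.70, camera adjusted p = 0.00443, and adjusted p = 0.192 with an estimated correlation). CXCL10, which draws activated T cells, had no count in WT and 62 counts over the K513R libraries, at least 21.3-fold higher against a floor of 3 counts over the group. CCL20, which draws cells bearing CCR6, went from no count to 128 counts, at least 44.0-fold higher, and CXCL5, a neutrophil chemokine, from 0.0256 ± 0.0222 to 1.31 ± 0.260 CPM. With the members at 0 set to their bound the list median stayed at 3.70. Of 27 antigen presentation genes, 17 rose and 2 fell, the immunoproteasome subunit PSMB9 and the class I transactivator NLRC5 (median 1.39, camera adjusted p = 0.00156, and adjusted p = 0.309 with an estimated correlation). TAP1, which carries peptides into the endoplasmic reticulum, rose from 14.5 ± 0.695 to 88.0 ± 8.37 CPM, a log2 fold change of 2.60 ± 0.10, and HLA-B by 2.50 ± 0.11. Counts were given to every overlapping gene without regard to strand, and 47.3% of the exonic length of HLA-B is shared with DHFRP2, 14.2% of that of TAP1 with PSMB8-AS1 and 23.1% of that of IFI6 with LINC02574. Of 39 interferon-stimulated genes, 25 rose and 9 fell (median 1.00, camera adjusted p = 0.00895, and adjusted p = 0.192 with an estimated correlation). MX2, an antiviral GTPase, rose from 0.762 ± 0.187 to 17.2 ± 0.816 CPM, IFI6 from 3.04 ± 0.680 to 53.9 ± 3.72 CPM and HERC5, the ligase for ISG15, by 4.28 ± 0.52 on the log2 scale. Of 21 immune checkpoint ligands and related surface genes, 14 rose and 3 fell, CEACAM1, ULBP1 and PVR (median 0.71, camera adjusted p = 0.0331, and adjusted p = 0.206 with an estimated correlation). ULBP2, a ligand of the NKG2D receptor, rose by 4.29 ± 0.14, and CD80, a ligand of CD28 and CTLA4, by 4.12 ± 0.29, with 24.8% of its exonic length shared with TIMMDC1. VTCN1 (B7-H4) had 2 counts in WT and 147 in K513R, a ratio of 75.7 (95% counting interval 20.6 to 631), and its fitted log2 fold change was 5.41 without WT replicate 1 and 8.62 without WT replicate 3. Intervals and floors of this kind cover counting error only.

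Of 20 genes that sense double-stranded RNA, 10 rose and 6 fell, and the group did not pass the test against other genes (median 0.28, camera adjusted p = 0.487). OASL rose from 2.26 ± 0.386 to 23.7 ± 2.74 CPM and the Z-nucleic acid sensor ZBP1 from 0.0264 ± 0.0457 to 0.340 ± 0.0822 CPM, a log2 fold change of 3.56 that was 2.94 without WT replicate 1 and 7.06 without WT replicate 3. IRF7, the transcription factor that amplifies interferon production, fell by 5.11 ± 0.83 on the log2 scale, from 2.69 ± 0.585 to 0.0742 ± 0.0695 CPM (11 counts over the K513R libraries), and the change was -5.90 without K513R replicate 3. The count table has no repeat element rows, so endogenous retroelements were read only from annotated genes. Of 14 genes of endogenous retrovirus or retroelement origin, 9 rose and 2 fell, ERVFRD-1 and ERVK3-1 (median 1.14, camera adjusted p = 0.0397, and adjusted p = 0.260 with an estimated correlation). This call was lost without WT replicate 3 (adjusted p = 0.0582). ERVV-1 and ERVV-2, envelope genes on chromosome 19, had no count in WT and 143 and 60 counts in K513R, at least 49.1-fold and at least 20.6-fold higher. The level of ERVV-1 in K513R varied between libraries (0.964 ± 0.597 CPM), and its fitted log2 fold change of 8.58 was 7.94 without K513R replicate 3. ERVMER34-1 went from 0.0338 ± 0.0133 to 4.53 ± 0.574 CPM. Of 31 genes that silence retroelements, 20 fell and 6 rose (median -0.87, camera adjusted p = 0.00156, and adjusted p = 0.192 with an estimated correlation). UHRF1, which guides maintenance DNA methylation, fell by 3.55 ± 0.11 and the DNA methyltransferase DNMT3A fell by 3.39 ± 0.13, while the cytidine deaminase APOBEC3F, a restriction factor rather than a chromatin silencer, rose by 5.03 ± 0.19. In the MeRIP inputs, compared below, UHRF1 and DNMT3A had log2 fold changes of 0.02 and -0.05 that did not pass (edgeR adjusted p = 0.9083 and 0.8922). Of 37 KRAB zinc finger genes, many of which bind retroelements, 21 rose and 9 fell (median 0.44, camera adjusted p = 0.133; 23 and 2 with upper-quartile factors), and ZNF850 went from no count to 434 counts, at least 149-fold higher. Markers of fibroblasts, endothelium and blood cells, which LoVo cells are not known to express, rose as well, 15 of 23 higher and 1, COL3A1, lower (median 1.08, camera adjusted p = 0.00957, and adjusted p = 0.309 with an estimated correlation). Their levels stayed low, with the monocyte gene CD14 at 2.77 ± 0.55 CPM (log2 fold change 3.53, and 4.20 without WT replicate 1), the T cell gene CD3D at 2.09 ± 0.25 CPM and the endothelial cadherin CDH5 at 0.807 ± 0.348 CPM in K513R. Olfactory receptor genes had 0.0555 ± 0.015 CPM per kilobase of exon in WT and 0.226 ± 0.00209 in K513R, and genes with at least 1 count numbered 37500 ± 518 and 44100 ± 826. Both were higher in K513R together with the immune, retroviral and cell-type marker genes of low level.

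Cell cycle and housekeeping groups were lower in K513R. Of 15 mitochondrially encoded genes, 13 fell and the rRNA genes MT-RNR1 and MT-RNR2 did not pass the test (median -4.63, camera adjusted p = 1.22e-06, and adjusted p = 0.309 with an estimated correlation). MT-ND2, a complex I subunit, fell by 6.14 ± 0.22, from 2623 ± 820 to 37.3 ± 11.3 CPM, MT-ATP6 fell by 6.12 ± 0.18 and MT-CO3 fell by 6.06 ± 0.20. Of 36 replication-dependent histone genes, 30 fell and 4 rose, H3C3, H4C9, H2BC3 and H4C11 (median -3.28, camera adjusted p = 3.08e-08, and adjusted p = 0.206 with an estimated correlation). The linker histone genes H1-4 and H1-5 fell by 6.19 ± 0.16 and 5.94 ± 0.15, and H2AC4 fell by 5.73 ± 0.20. Of 34 E2F and cell cycle genes, 30 fell and 3 rose, E2F1, FOXM1 and BIRC5 (median -1.40, camera adjusted p = 6.83e-08, and adjusted p = 0.192 with an estimated correlation). The mitotic genes CCNB1 and PLK1 fell by 2.67 ± 0.10 and 2.58 ± 0.11, and MYBL2, a transcription factor of the G1 to S step, fell by 2.57 ± 0.10. Of 24 genes of the E2F4 and H3K4 methyltransferase complexes, 19 fell and 2 rose, LIN37 and CXXC1, or 16 and 4 with upper-quartile factors (median -1.01, camera adjusted p = 0.000116, and adjusted p = 0.192 with an estimated correlation). LIN54, the DNA-binding part of the MuvB complex, fell by 3.14 ± 0.11, TFDP2, a partner of E2F proteins, fell by 2.97 ± 0.12 and WDR82, a subunit of the SETD1 complexes, fell by 2.08 ± 0.12. Of 47 ribosomal protein genes, 27 fell and 8 rose (median -0.70, camera adjusted p = 0.00107, and adjusted p = 0.309 with an estimated correlation), with RPL23, RPL11 and RPL38 falling by 2.62 ± 0.10, 2.49 ± 0.11 and 2.30 ± 0.20.

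Of 21 Wnt targets, 16 fell and 4 rose, MMP7, LGR5, PROX1 and SOX9 (median -0.95, camera adjusted p = 0.00156, and adjusted p = 0.192 with an estimated correlation). AXIN2, a negative feedback gene of the pathway that shares 25.3% of its exonic length with another gene, fell by 3.85 ± 0.10, from 262 ± 26.5 to 18.2 ± 0.713 CPM, and MYC fell by 3.80 ± 0.11, from 132 ± 14.1 to 9.49 ± 0.276 CPM, while the metalloprotease MMP7 rose from 0.0276 ± 0.024 to 0.933 ± 0.242 CPM (log2 fold change 5.00, and 4.38 without WT replicate 1). In the MeRIP inputs, compared below, AXIN2 and MYC had log2 fold changes of -0.09 and 0.10 that did not pass (edgeR adjusted p = 0.5015 and 0.4647). Of 25 hypoxia and glycolysis genes, 13 fell and 7 rose (median -0.81, camera adjusted p = 0.0213, and adjusted p = 0.497 with an estimated correlation). The glycolytic enzymes LDHA, HK2 and ENO1 fell by 4.56 ± 0.10, 3.23 ± 0.12 and 3.16 ± 0.10. Of 24 genes of the unfolded protein and integrated stress responses, 15 fell and 5 rose, DNAJB9, ATF3, SDF2L1, HSPA5 and STC2 (median -1.03, camera adjusted p = 0.0213, and adjusted p = 0.192 with an estimated correlation). CEBPB fell by 3.02 ± 0.34, DDIT4, an inhibitor of mTORC1, fell by 2.91 ± 0.10 and TRIB3 fell by 2.41 ± 0.20. In the m6A machinery 14 of 23 genes fell and 7 rose, and the group did not pass (median -1.08, camera adjusted p = 0.0547). The m6A readers IGF2BP2 and IGF2BP1 fell by 3.57 ± 0.09 and 2.32 ± 0.23, and RBM15B, an RNA-binding subunit of the methyltransferase complex, rose by 2.50 ± 0.09, with 20.0% of its exonic length shared with DCAF1. The inputs gave IGF2BP2 a log2 fold change of -0.18 that did not pass (edgeR adjusted p = 0.2048), and RBM15B rose there by 0.70. Of 21 m6A machinery genes tested in the inputs, 7 rose and 1 fell (median 0.12, camera adjusted p = 0.2225). Where 5 or fewer members of a group went against it, they were named after their values were seen.

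The remaining groups did not pass camera. Of 16 intestinal differentiation markers, 8 rose and 4 fell, CDX2, CA1, VIL1 and MUC5AC (median 1.14, adjusted p = 0.359), and the chloride anion exchanger SLC26A3 went from 0.0548 ± 0.0341 to 4.87 ± 0.341 CPM. Of 25 p53 targets, 14 rose and 9 fell (median 0.40, adjusted p = 0.538), with TP53INP1 rising by 1.63 ± 0.14. Of 24 cholesterol biosynthesis genes, 9 rose and 10 fell (adjusted p = 0.694), the list median was -0.18 and turns positive with upper-quartile factors, and the mean was 0.04. In this list SC5D rose by 2.36 ± 0.10. Of 23 epithelial and mesenchymal genes, 11 rose and 8 fell (median 0.56, adjusted p = 0.929), and the epithelial keratin KRT19 fell by 3.69 ± 0.13, from 1321 ± 258 to 102 ± 12.5 CPM. Of 18 NF-kB response genes, 9 rose and 3 fell, NFKB1, NFKBIA and ICAM1 (median 0.58, adjusted p = 0.0871). Of 24 immediate early genes, 13 rose and 8 fell (median 0.79, adjusted p = 0.212), and FOS rose by 4.62 ± 0.17, from 2.21 ± 0.510 to 54.5 ± 5.04 CPM. Adjusted over the list alone, the counts of members higher and lower were those given over all genes for each RNA-seq list except antigen presentation (16 higher), retroelement silencing (21 lower) and p53 targets (10 lower). With an estimated correlation 0 of the 24 lists passed camera and 6 had an unadjusted p under 0.05, while 23 passed fry.

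**Figure D2:**
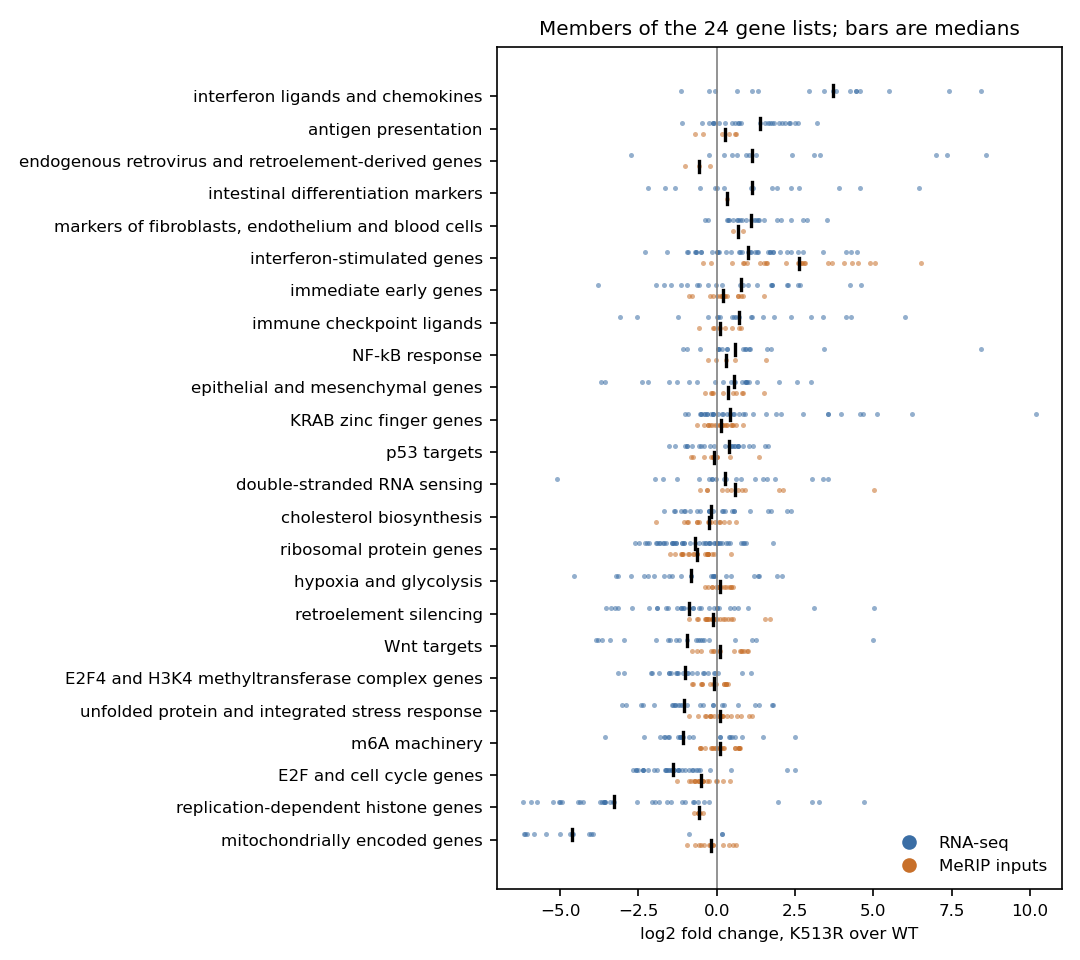
Log2 fold change, K513R over WT, of every measured member of the 24 gene lists in the RNA-seq libraries (blue) and the MeRIP inputs (orange), with a black bar for the median of each list. RNA-seq medians run from -4.63 for mitochondrially encoded genes to 3.70 for interferon ligands and chemokines, and the median of cholesterol biosynthesis genes in RNA-seq and those of p53 targets and of the E2F4 and H3K4 complex genes in the inputs change sign with the scaling.

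The MeRIP inputs are unenriched poly(A) RNA of the same genotypes, and summing their counts per gene over the deposited peaks gave another reading of expression. This comparison was added after the tables were seen. In the inputs 21 of 25 interferon-stimulated genes rose, and IFITM1, IFITM2, IFITM3 and PARP12 did not pass the test (median log2 fold change 2.63, camera adjusted p = 3.46e-25, and adjusted p = 0.00654 with an estimated correlation). Adjusted over the list alone, 22 rose. IFI44L (chromosome 1, 78619902 to 78646145) rose from 4.64 ± 0.969 to 430 ± 76.8 CPM, a log2 fold change of 6.53 ± 0.32, IFI44 by 5.04 ± 0.43 and the translation inhibitor IFIT3 by 4.90 ± 0.14, from 48.5 ± 6.55 to 1457 ± 187 CPM. The antiviral GTPase MX1 rose by 4.32 ± 0.34 in the inputs and had a log2 fold change of 0.03 in RNA-seq (edgeR adjusted p = 0.825), and ISG15, a ubiquitin-like modifier, rose by 2.59 ± 0.16 in the inputs against 0.02 in RNA-seq (edgeR adjusted p = 0.864). In 1 edgeR model over both assays the change of 17 of the 25 genes was lower in RNA-seq than in the inputs and that of 4 was higher. Of 12 genes that sense double-stranded RNA, 7 rose in the inputs (median 0.57, camera adjusted p = 0.000461, and adjusted p = 0.0815 with an estimated correlation), led by OASL with 5.02 ± 0.51.

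Ribosomal protein genes fell in the inputs, 14 of 22 lower (median -0.63, camera adjusted p = 4.7e-10, and adjusted p = 0.0219 with an estimated correlation; 18 lower and 1 higher adjusted over the list alone). Of 18 E2F and cell cycle genes 11 fell and 1, MCM3, rose (median -0.51, camera adjusted p = 0.000362, and adjusted p = 0.0815 with an estimated correlation; 12 lower adjusted over the list alone). Of 6 histone genes 4 fell, H4C5, H1-5, H4C3 and H4C8 (median -0.57, camera adjusted p = 0.00382, and adjusted p = 0.185 with an estimated correlation). Mitochondrially encoded genes had a median of -0.18, with MT-ND5 and MT-ND6 higher and MT-CO3 lower among 14 (camera adjusted p = 0.591). The other lists past camera in RNA-seq did not pass in the inputs, where interferon ligands and chemokines were not measured. Wnt targets had 5 of 15 higher and 0 lower (median 0.10), and retroelement-derived genes 0 of 3 higher and 1 lower (median -0.57). Hypoxia and glycolysis genes had 1 of 14 higher and 0 lower. Retroelement silencing genes had 3 of 23 higher and 6 lower, and antigen presentation genes 2 of 6 higher and 1 lower. In the inputs METTL14 rose by 0.71 ± 0.17 and WTAP by 0.72 ± 0.11, METTL3 had a log2 fold change of -0.12 ± 0.12 (edgeR adjusted p = 0.495) and SETD1A one of 0.29 ± 0.16 (edgeR adjusted p = 0.222). Over all 7945 genes tested in the inputs, 1065 rose and 1040 fell in the edgeR test. Without WT replicate 1, 2 or 3 the number higher was 674, 665 or 697, and without WT replicate 2 the number lower was 663. With library-size scaling the share of calls that were higher moved from 50.6% to 66.6%. Across the 7924 genes measured in both assays the log2 fold changes correlated with Pearson r = 0.31 and Spearman rho = 0.32, and genes are not independent replicates.

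**Figure D3:**
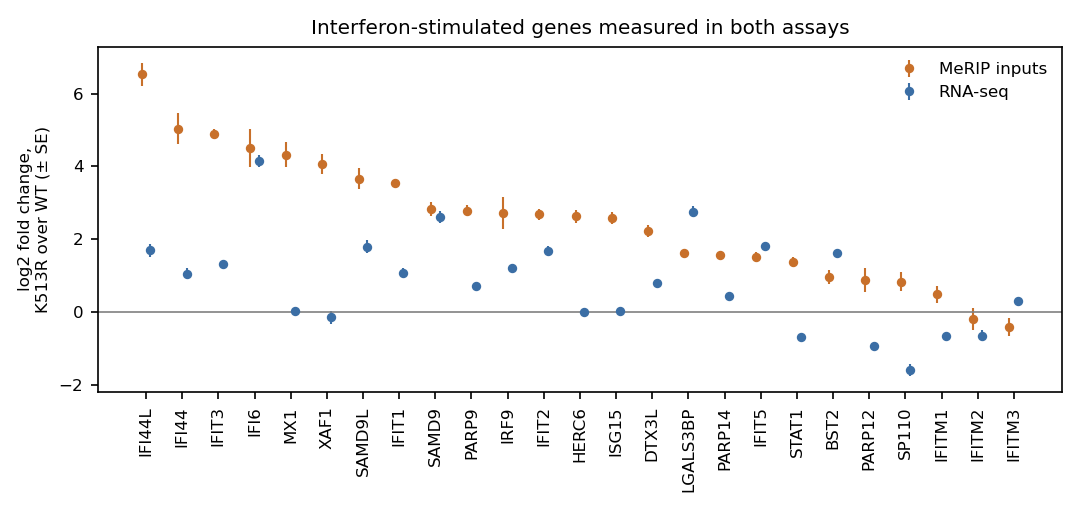
Log2 fold change, K513R over WT (± SE), of the 25 interferon-stimulated genes measured in both assays, in the MeRIP inputs (orange) and in RNA-seq (blue), ordered by the value in the inputs. The inputs reach 6.53 for IFI44L, where RNA-seq gave 1.70, and for MX1, HERC6 and ISG15 the RNA-seq value lies between 0.01 and 0.03.

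The next comparison asked how m6A differs between the genotypes. The deposited table names 24302 peaks after WT and 15406 after K513R. Of the WT peaks 10875 (44.7%) overlapped a K513R peak by at least 1 base, and of the K513R peaks 11907 (77.3%) overlapped a WT peak. Whether sequencing depth differed between the genotypes, and with it the number of peaks, was not tested. In the test of IP over input between genotypes, the peaks with the largest loss lay in USP3, CES3, PGBD4, ELOVL7, GJB5 and CITED2. CITED2 encodes a CBP/p300-binding regulator, and its last-exon peak (chromosome 6, 139372491 to 139372850, minus strand, GRCh38) went from a log2 IP over input of 1.57 ± 0.17 in WT to -1.40 ± 0.74 in K513R, a difference of -3.55 ± 0.61 (edgeR adjusted p = 0.000495) over 167 IP and 19 input counts in WT and 25 and 42 in K513R. The peaks in ELOVL7, a fatty acid elongase (chromosome 5, 60754574 to 60754784), and PGBD4, a domesticated transposase (chromosome 15, 34104980 to 34105220), both in last exons, differed by -3.66 ± 0.88 and -3.69 ± 0.80. The peak in CES3, a carboxylesterase (chromosome 16, 66972494 to 66972854), differed by -3.76 ± 1.11. With 1 replicate left out the CES3 value was -3.08 (WT replicate 2) to -4.47 (WT replicate 3) and also moved without K513R replicate 1, that of PGBD4 was -2.93 without K513R replicate 2, and that of ELOVL7 was -2.92 without K513R replicate 3. The peaks in USP3, a histone deubiquitinase (chromosome 15, 63591072 to 63591373), and GJB5, a connexin (chromosome 1, 34757422 to 34757600), differed by -3.84 ± 1.00 and -3.65 ± 0.94 over 2 and 1 WT input counts. Their inputs were higher in K513R by 3.2 and 5.85 on the log2 scale, with IP counts of 64 in WT and 22 in K513R for USP3 and of 12 and 31 for GJB5, so the GJB5 difference goes with a higher input and not with fewer IP counts. The inputs of the other 4 of these peaks were higher by 0.96 (ELOVL7), 1.13 (PGBD4), 1.59 (CES3) and 1.70 (CITED2). The calls of USP3 and GJB5 were lost without any one of the WT replicates 1, 2 and 3 and without K513R replicate 2. With 1 replicate left out the USP3 difference ran from -4.7 to -3.28 and that of GJB5 from -5.33 to -3.21.

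The largest gains rest on input counts near 0. A peak near the 5′ end of NUS1, a subunit of the enzyme that makes dolichol (chromosome 6, 117675468 to 117675739), had 55 IP and 14 input counts in WT against 43 and 0 in K513R, and an overlapping peak of the other list had 54 and 11 against 43 and 0, a call lost without WT replicate 1 or 3. A last-exon peak of DBNL, an actin-binding adaptor (chromosome 7, 44068676 to 44069246), had 116 and 12 against 56 and 0, and its call was lost when any library pair but K513R replicate 1 was left out. A pair of overlapping peaks in MYADM (chromosome 19, 53874435 to 53874913, and 53874554 to 53874764) had 61 and 17 against 83 and 1, and 56 and 14 against 77 and 1, and the call of the latter was lost without WT replicate 3. The peak in C18orf54 (chromosome 18, 54380067 to 54380308) went from a log2 IP over input of -1.41 ± 0.30 to 2.18 ± 1.48, with a difference of 4.26 ± 0.89 (edgeR adjusted p = 0.00173) that was 9.48 without K513R replicate 1 and 3.35 without K513R replicate 3. In the genes of the methyltransferase complex, a last-exon peak of METTL14 (chromosome 4, 118710066 to 118710247) fell by 1.46 ± 0.23 and an overlapping one fell by 1.23 ± 0.23, while the other 3 tested METTL14 peaks, at -0.18, 0.32 and 0.17, did not pass. In WTAP a last-exon peak (chromosome 6, 159755243 to 159755483) fell by 1.70 ± 0.32 and an overlapping one fell by 1.85 ± 0.30, a pair near the 5′ end fell by 0.84 ± 0.24 and 0.82 ± 0.24, and the next pair rose by 0.83 ± 0.27 and 0.89 ± 0.27. In SETD1A 1 of 5 tested peaks passed, at -1.18 ± 0.37, and no peak in METTL3 passed the test (5 tested peaks with differences from -0.67 to 0.67). The METTL3 value of 0.67 is that of the same stretch named in both lists. On the log2 scale, inputs of the called METTL14 peaks were higher in K513R by 0.75 and 0.78. That of the called SETD1A peak was higher by 0.73, and those of the last-exon WTAP pair by 1.01 and 1.24. These losses thus go in part with a higher input. Inputs of the other called WTAP pairs moved by 0.13 and 0.12 and by -0.24 and -0.29. Among the 66 peaks of ribosomal protein genes 21 were higher, and among the 70 of E2F and cell cycle genes 19 were higher and 4 lower. Peaks of Wnt targets went the other way, 11 of 50 lower and 3 higher, as did those of the m6A machinery, 20 of 99 lower and 13 higher. Interferon-stimulated genes had 8 higher and 11 lower peaks of 117. These counts per list were set against no other genes by a test, and overlapping peaks named after WT and after K513R count separately in them.

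Over all tested peaks, 3543 of 27252 were higher and 2620 lower in K513R in the edgeR test of the genotype by IP interaction, so 42.5% of the calls were lower. The balance reversed with the list a peak was named for. Of 16140 tested peaks named after WT 1236 were higher and 2022 lower, and of 11112 named after K513R 2307 were higher and 598 lower. The names imply a call in the libraries of that genotype, which favours strong IP over input there. Such a lean is thus built in by the selection of peaks and is no evidence on m6A. Overlapping peaks named after WT and after K513R count separately here. A refit on non-overlapping peaks alone, with new scaling factors, called 2617 of 17746 higher and 1627 lower. That set includes all peaks named after WT, of which the main fit called 2022 lower. The refit itself thus moved the balance, not only the removal of overlaps. With input and IP paired per RNA the test called 4611 higher and 3453 lower. Scaling by library size alone gave 1813 higher and 3928 lower (68.4% lower), so the balance of gains and losses depends on the scaling. The authors' deposited table gives 3086 higher and 5180 lower of 39708 peaks at the same threshold (62.7% lower). It covers more peaks and its model and scaling are not known here, so its balance cannot be put down to scaling alone. All of the 5392 peaks called both here and in the authors' deposited table had the same sign. Both comparisons rest on the same libraries (Pearson r = 0.987 of the log2 differences across tested peaks), so this is no independent support. Without WT replicate 1, 2 or 3 or K513R replicate 2 the counts fell to 1180 and 868, 1383 and 972, 1252 and 891, and 1893 and 1376 for higher and lower peaks.

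The changed peaks differed in where they lie in the transcript, read along the merged exons of each gene because UTR and coding annotation were not used here. Among peaks of multi-exon genes, 10.1% of the higher peaks and 55.6% of the lower peaks were centred in the last exon, against 43.8% of the peaks not called. Where log2 IP over input, scaled within the tested peaks, was positive in both genotypes, only 468 such peaks were higher and 624 lower. Of these, 14.5% and 57.5% were centred in the last exon. For peaks that do not overlap each other across the lists the odds ratio of lower against higher was 12.1 (Fisher's exact test, two-sided, p = 2.11e-238), and neighbouring peaks are not independent. Of the higher peaks 62.3% lay in the 5′ part of the exonic length (relative position under 0.333), and of the lower peaks 32.5%. From the 5′-most to the 3′-most of 5 equal bins of the exonic length the median difference in IP over input went from 0.47 to -0.28. The IP alone went from 0.29 to -0.12 and the input from -0.09 to 0.13. In the peak lists themselves, 46.6% of WT peaks and 39.1% of K513R peaks of multi-exon genes were centred in the last exon, and 35.6% and 42.2% of all peaks in the 5′ part.

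**Figure D4:**
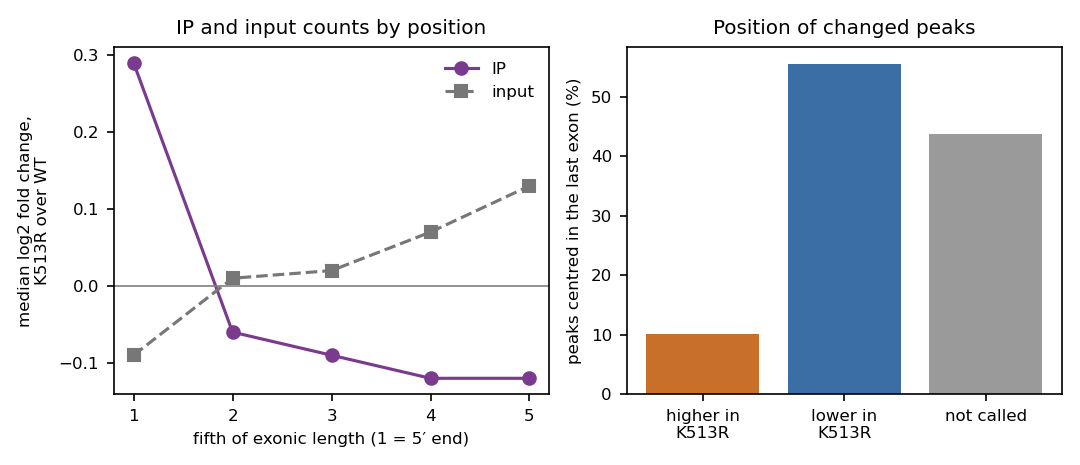
Left, median log2 fold change, K513R over WT, of IP counts (purple) and input counts (grey) of the tested peaks in 5 equal bins of the exonic length, from the 5′ end (1) to the 3′ end (5). Right, percent of peaks of multi-exon genes centred in the last exon, which is 10.1 for higher peaks, 55.6 for lower peaks and 43.8 for peaks not called, with no error bars because each bar is a share of all peaks of its class.

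The last comparison asked whether RNA levels moved with m6A. Genes with a higher m6A peak in K513R were lower in RNA-seq, with a median log2 fold change of -0.90 over 1921 genes. It was -0.37 for the 10784 genes with any deposited peak, whether or not that peak was tested. Against all genes this set was lower (camera p = 4.86e-15, and p = 0.019 with an estimated correlation), as it was against genes with a peak only (camera p = 3.55e-06). Of these genes 69.6% were called lower in RNA-seq, against 48.3% of the other genes with a peak (Fisher's exact test, two-sided, odds ratio 2.45, adjusted p = 3.83e-65, with genes that are not independent). Genes with a lower m6A peak had a median of -0.33 over 1785 genes, and 32.0% were called higher against 30.4% of the others (odds ratio 1.08, adjusted p = 0.249). Against all genes this set was lower (camera p = 0.00333, and p = 0.112 with an estimated correlation), and against genes with a peak only it was not (camera p = 0.733, in the other direction). The sets share 328 genes. In the MeRIP inputs the median log2 fold change was 0.23 for genes with a lower peak and -0.20 for genes with a higher peak, and since the input is also the denominator of IP over input these values are not independent of the peak calls.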

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

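The joint model of both assays and the tests of the mitochondrially encoded genes in the inputs, of gene families made at the endoplasmic reticulum, of single libraries, of the scaling of peaks and of peak position were chosen after the results were seen.

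The effect of K513R differed between RNA-seq and the MeRIP inputs by the assay by genotype term of a joint edgeR model. Of 7924 genes measured in both, 2419 changed upward and 2619 downward in RNA-seq relative to the inputs. Among interferon-stimulated genes 17 of 25 had a lower change in RNA-seq than in the inputs, and among mitochondrially encoded genes 13 of 14 did.

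In RNA-seq most genes differed between the genotypes, with mitochondrial, histone and cell cycle RNAs lower and 7SL RNA higher in K513R. A few abundant transcripts are argued against, since 24146 genes passed the test without the 7SL, 7SK and mitochondrial genes and with library size as scaling. A genotype effect on mitochondrial RNA of like size in both assays is argued against too, since the median change of these genes in the inputs was -0.18. The inputs are poly(A) RNA counted in peaks and RNA-seq is total RNA, so an effect on total mitochondrial RNA alone stays open. Genes of families made at the endoplasmic reticulum exceeded those of families made on free ribosomes by 1.25 in median log2 fold change over 478 and 275 genes, and over the 185 and 180 genes measured in both assays by 0.91 in RNA-seq and 0.39 in the inputs (permutation p = 1e-04 for each, the smallest possible), so a candidate explanation is a difference in which RNA entered the K513R RNA-seq libraries. The permutation moves genes, which are not independent, so its p does not measure the spread between libraries. The labels name no batch, so library making and a genotype effect in those cultures cannot be told apart, and reads from genomic DNA or unspliced RNA stay open too, since 32.6% of the protein-coding genes called higher had an excess per kilobase under 3 times that of olfactory receptor genes. The 10 splits of the 6 libraries are too few for a share under 0.05, with 23800 genes called by the real split, 1 split reaching that number and 0 genes called by edgeR in any other (at most 54 at an unadjusted p under 0.05). Every other split mixes the genotypes, so a genotype difference widens the spread within its groups. The calls of such splits are therefore no reference for chance.

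Interferon-stimulated genes rose in the K513R inputs by a median of 2.63 and, for MX1, ISG15, HERC6 and XAF1, did not pass the test in RNA-seq. Counting in peaks found only in K513R is argued against, since the median in WT-called peaks was 2.63, and a single library is argued against, since the lowest median with 1 library left out was 2.52. An interferon response of the cultures used for MeRIP may underlie the rise, and an effect of the genotype and a difference between cultures stay open, since the labels give no culture or batch. The 10 splits are too few for a share under 0.05, with 2105 input genes called by the real split, 1 split reaching that number and 0 called by edgeR in any other (at most 325 at an unadjusted p under 0.05). Here too the other splits mix the genotypes, so their calls are no reference for chance.

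In m6A, losses lay toward the last exon and gains toward the 5′ end, while the balance of losses and gains moved with the scaling, by 25.9 percentage points in the share of lower peaks over 3 scalings. It also moved with the list, with 1236 higher and 2022 lower among peaks named after WT and 2307 and 598 among those named after K513R. Selecting peaks by a call in 1 genotype favours that genotype, so this lean is no evidence on m6A. A change of the input as the sole source is argued against, since 22.8% of peaks with an input change under 0.25 were called against 22.6% of all tested peaks, and the odds ratio of the last exon among such peaks was 9.65. The input may still contribute elsewhere. Its median log2 change was -0.29 for higher peaks, 0.37 for lower peaks and 0.02 for peaks not called. Calls were more frequent among weakly enriched peaks. Of 5 equal bins by enrichment, the least enriched (median log2 IP over input -0.61) held 1190 higher and 781 lower peaks. The most enriched (median 1.27) held 254 higher and 258 lower, so many gains lie in peaks with weaker enrichment than the others. These log2 values are scaled within the tested peaks, so a negative one does not mean IP below input. Weaker enrichment in the K513R IP libraries cannot be told apart from a change in m6A, since the median difference in the most enriched of these bins minus that in the least enriched was -0.12, between the bounds set for either reading. A shift of m6A along the transcript may be weighed only with that left open. The 10 splits are too few for a share under 0.05, with 6163 peaks called by the real split, 1 split reaching that number and 0 called by edgeR in any other (at most 434 at an unadjusted p under 0.05). For peaks as well the other splits mix the genotypes, so their calls are no reference for chance.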

How the results depend on the processing

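The comparison of the inputs, the settings without 7SL, 7SK and mitochondrial genes, with non-overlapping peaks and with genes with a peak only were chosen after seeing the data. Of the values of 74 named genes under the alternatives, 1087 kept their direction and side of the threshold. The exceptions were 6 reversed and 2 newly past it, all of E2F4. Its log2 fold change was -0.05 with library size, -0.04 without the low-count filter, -0.10 to 0.15 with 1 replicate left out (-0.09 and -0.10 without WT replicate 1 and 2, -0.02 and -0.03 without K513R replicate 1 and 3), 0.30 with upper-quartile factors and 0.36 without the 7SL, 7SK and mitochondrial genes and with library size as scaling. The lists that passed with an estimated correlation were 0 higher and 0 lower, and fry called 12 higher. Of the values of the 12 named peaks, 106 kept their side of the threshold and 18 kept their direction but lost the call, in peaks of USP3, GJB5, NUS1, DBNL and MYADM. In the inputs an estimated correlation left 1 list higher and 1 lower, and fry called 4 and 5. With 1 replicate left out, input genes higher ran from 665 to 1247 and lower from 663 to 1392, and peaks higher from 1180 to 4172 and lower from 868 to 3337. Library size gave 1813 higher peaks, the stronger peaks by the authors' score 928 higher and 580 lower, FDR 0.01 1392 and 914, and non-overlapping peaks 2617 and 1627. Among these stronger peaks, 32.8% of WT and 40.4% of K513R peaks lay at a relative position under 0.333, 34.9% and 29.9% in the matching 3′ part, and 53% and 44.9% of those of multi-exon genes in the last exon. Of these stronger peaks 6296 of WT and 5987 of K513R overlapped the other list. Of all peaks, 6048 and 6057 did with a reciprocal overlap of 50%. The stronger peaks, FDR 0.01 and the non-overlapping peaks hold fewer peaks by construction, and elsewhere the cause was not tested. The stronger and the non-overlapping peaks were also refitted with new scaling factors, so their balance is not that of the main fit. Genes with a lower m6A peak had a camera p of 0.112 with an estimated correlation and 0.733 in the other direction against genes with a peak only. Replicate numbers did not pair the genotypes, and a block on them kept 89 of 89 named genes and lists on their side of the threshold. The 15 alternatives of the retroelement test were not run, since the table has no repeat elements. Of simulated 2-fold changes, 41.4% were found in peaks, where only 200 features were changed.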

Other observations

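The comparison of the inputs and the test of gene families were chosen after the data were seen, and so were the genes named here.

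Outside the fixed lists, the inputs held further genes that rose in K513R. NT5E (CD73), an ectoenzyme that makes adenosine, rose from 1.61 ± 1.45 to 27.4 ± 8.03 CPM (mean ± SD, n = 3), a log2 fold change of 3.94 ± 0.57, and by 3.93 in RNA-seq. COL17A1, a collagen of hemidesmosomes, rose by 4.21 ± 0.54, the cytokine receptor gene IL7R by 3.62 ± 0.50 and RAB27B, a GTPase of secretory vesicles, by 2.99 ± 0.16. ANKRD1 rose by 3.00 ± 0.26 in the inputs and fell by 1.63 in RNA-seq. Among the genes that fell in the inputs, SCG2, a granin of secretory granules, fell by 3.06 ± 0.48, PCP4 fell by 2.98 ± 0.43, and CHCHD10, a mitochondrial intermembrane protein, fell by 2.02 ± 0.30.

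The gene families that follow were counted at a mean of at least 5 CPM. Of 150 SLC genes without SLC25 73 rose and 49 fell in RNA-seq (median log2 fold change 0.25), and of 116 TMEM genes 58 rose and 35 fell (median 0.28). In RNA-seq 9 of 10 TMED genes, which carry cargo between the endoplasmic reticulum and the Golgi, rose, with a median log2 fold change of 1.26. Of 22 HNRNP genes, which bind nuclear RNA, 21 fell (median -1.90). Of 44 NDUF genes of respiratory complex I 31 fell (median -1.27), as did 54 of 75 mitochondrial ribosomal protein genes (median -0.96) and 33 of 47 proteasome genes (median -1.07). In the inputs 12 of 19 HNRNP genes fell (median -0.43) and of 6 TMED genes 1 rose and 1 fell.

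For the 24 lists, the real split of the RNA-seq libraries called 15 by camera with the preset correlation, 1 split of 10 reached that number, and the highest of the other splits called 13. For genes with a lower m6A peak, 4 of the 10 splits gave a camera p as small as the real 0.00333, with 0.0014 as the smallest of the others. The splits are too few for a share under 0.05, and all but the real one mix the genotypes.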
